A study of Mus musculus with 14 samples.

How the data were processed

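Embryonic mouse kidneys were compared between embryos carrying Foxd1cre, a Cre driver active in stromal progenitors, with floxed Tcf21 alleles (mutants) and Foxd1cre embryos with wild-type Tcf21 (controls). The libraries were of several kinds: single-cell RNA at E14.5 and at E18.5 (2 control and 2 mutant libraries at each stage, 1 female and 1 male of each), single-nucleus chromatin accessibility at E14.5 (1 control and 1 mutant library, males) and whole-kidney RNA at E18.5 (2 control and 2 mutant kidneys, males). The single-cell libraries pooled 2, 4, 3 and 1 embryos at E14.5 and 2, 2, 2 and 1 embryos at E18.5 (control female, control male, mutant female, mutant male), each accessibility library pooled 4, and each whole-kidney library came from 1 embryo. Cells were sorted for the Foxd1 lineage after dissociation with a cold-active protease, per the labels' protocols, and the mice of the single-cell libraries carried mTmG, a reporter that switches from tdTomato to EGFP after Cre activity. A library was the replicate throughout, so p-values measure the spread between libraries, which are pools of embryos or, for the mutant males and all whole kidneys, single embryos. The series' design text gives E18.5 as the age of the accessibility nuclei in one place while the labels give E14.5, and E14.5 was used.

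The authors deposited UMI counts per gene and cell barcode from Cell Ranger 6.1.0 at E14.5 and 6.0.1 at E18.5, per the file headers, with 10x Genomics 3′ version 3 chemistry per the labels' protocols. They deposited accessibility counts per peak and barcode from Cell Ranger ATAC 2.1.0, per the file headers, with the peaks called separately in each library. The whole-kidney table holds FPKM per gene symbol that the authors made with HISAT2 and Cufflinks, and the build was mm10, both per the submitters' processing notes; versions of these tools, the annotation, the strand setting and any filter were not given in the sources used here. Its columns name the group but no sample number. FPKM columns give no read totals, so the depth of those libraries is unknown. Levels of abundant genes lay closer together in that table than in single cells: genes at 1 to 10, 10 to 100, 100 to 1000 and over 1000 CPM in all retained cells of the E18.5 control libraries had median FPKM of 12.1, 27.4, 42.9 and 31.7 (Spearman 0.900 across 21489 genes, which are not independent replicates). Whether this alters changes between kidneys is not known: for genes called in E18.5 stroma at under 20, 20 to 100 and over 100 CPM, whole-kidney changes had slopes of 0.149, 0.236 and 0.255 on stromal changes, which do not fall with abundance. Among its symbols, 27 had been turned into dates and were left out, which left 24313 genes.

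Single cells were kept with at least 1000 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with scrublet in scanpy 1.11.5. Its automatic threshold marked 0.0207% to 0.141% of cells in 5 of the 8 libraries, so in every library the highest scores were removed instead, at a rate of 0.8% per 1000 cells. This left 9498, 9718, 6177 and 7775 cells at E14.5 and 3439, 7109, 8897 and 3251 at E18.5, in the order given above. Cells were clustered with Leiden (igraph 0.11.9, resolution 1.0, seed 1) on 2000 variable genes, 30 principal components and 15 neighbours, leaving out Tcf21, Xist, Y-linked and mitochondrial genes and genes correlated above 0.15 with cell cycle scores. A cluster took the name of a marker list ("-like") when at least 3 of the list's genes and 50% of it were raised (log2 fold 0.5 against the other cells with 10 CPM added, detected in 20% of cells), at least 1 of them was among its 10 leading genes and no other class had more genes there. The perivascular, mesangial and renin cell lists were joined in a single class, called mural-like. Clusters were taken out where a list of epithelial, nephron, endothelial, macrophage, erythroid, neural, cartilage or muscle markers was the best supported, or where the median UMI count was under 1/3 of that of their own libraries, and all the others were summed as stromal cells (8804, 6687, 5134 and 1978 cells at E14.5, and 3180, 6321, 8603 and 3003 at E18.5).

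Raw UMI counts were summed per library over stromal cells, or over the cells of a class with at least 50 cells in every library of the stage, and tested with edgeR 4.0.16 (R 4.3.3; quasi-likelihood F test, TMM, filterByExpr, sex as covariate, all 8 libraries in 1 fit) with Benjamini-Hochberg adjustment at 0.05. The contrasts were mutant minus control at E14.5 and E18.5, and the difference of both effects. Levels are CPM with TMM factors. Whole-kidney values were tested with limma 3.58.1 with trend on log2(FPKM + 1) for genes at 1 FPKM or more in at least 2 kidneys; a log2 change on that scale understates the change of low genes. In all, 33 gene lists (19 of cell type markers and 14 of pathways) were tested with limma's camera with a preset correlation of 0.01, again with the correlation estimated from the data and with fry, and members were counted over all genes and adjusted over the list alone. Shares of cells were compared by a two-sided exact sign-flip permutation over the 4 pairs of equal stage and sex, whose smallest possible p is 0.125. Intervals on shares are 95% exact binomial intervals, those on ratios of counts are exact Poisson intervals, and both cover counting error only. Peak sets were compared by overlap of at least 1 bp, accessibility near a gene was taken within 5 kb of its RefSeq body (GRCm38.p6), and with 1 library per genotype no test was made: a list's median is given as a percentile among 10000 random lists matched on signal. Values near a gene sum only regions with peaks in both libraries and are scaled to the counts in such regions. Single peaks are scaled to the counts in all peaks. Accessibility counts were even in 89.5% and 88.9% of entries above 0, so single counts are not independent there and intervals are too narrow. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and DESeq2 1.42.0 as an alternative test, were also used.

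The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Tcf21 and Foxd1, then the 10 genes with the largest change each way (5 within a class and for the difference between stages) among those past the threshold, at 10 CPM or 1 FPKM on average and on the same side in both sexes or all kidneys, without Xist, Y-linked genes and unnamed gene models, and up to 4 members of each list with the smallest p. The values of some genes that the rule names are not reported here. In whole kidney the largest changes were mostly of small RNA genes, so the largest changes of other genes are given beside them, a choice made after seeing the data. Alternatives covered the test, size factors, low-value filters, covariate, cell filters, doublets, the cells summed, thinning, the libraries fitted, each library left out, class definitions, the pseudocount, set-test correlation and peak overlap; excluding small RNA genes, and genes at 0 in any kidney, were added after seeing the data.

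EdgeR, limma, camera and fry were tested on simulated data; the fits within classes and the sign-flip permutation were not. With 50 of 16811 genes changed at each fold in the E14.5 mutants of simulated stromal sums, edgeR called 98% at a fold of 2, 98% at 4, 98% at 0.5 and 100% at 0.25 with 17 false calls, and made 5 calls among 16822 unchanged genes. For the difference between stages, with the same genes changed at E14.5, it called 98%, 98%, 90% and 98% with 12 false calls, and made 2 calls among the unchanged genes. Every simulated library had the same means, taken from the controls of both stages, and the fitted dispersions. These figures thus do not cover differences between stages, sexes or pools. On simulated whole-kidney values limma called 76% at a fold of 2, 98% at 4, 78% at 0.5 and 92% at 0.25, with 9 false calls among 15131 genes. Camera with its preset correlation and fry each called 100% of 20 lists of 8 genes raised 1.5-fold in the E14.5 mutants of simulated stromal sums, and 0 of 40 unchanged lists. The genes were drawn independently of each other, so this does not show how either test behaves on correlated genes. Nephron genes used to gauge free RNA in stromal cells were those at 50 CPM or more in control nephron cells and at least 3 higher on the log2 scale than in stroma; a first setting of 200 CPM gave 6 genes and was lowered. Spliced or allele-specific reads were not analysed here, so the deleted part of Tcf21 was not examined.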

Results

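Kidneys of mouse embryos with and without a floxed Tcf21 in the Foxd1 lineage were profiled by single-cell RNA sequencing at E14.5 and E18.5 (2 control and 2 mutant libraries per stage), single-nucleus chromatin accessibility at E14.5 (1 library per genotype) and whole-kidney RNA sequencing at E18.5 (2 control and 2 mutant kidneys). The control female, control male, mutant female and mutant male libraries held 156524095, 202564480, 156266097 and 192991286 UMIs in 11049, 11995, 7867 and 9543 barcodes at E14.5. At E18.5 they held 37921145, 102916259, 121281869 and 37898009 UMIs in 4246, 8312, 10512 and 3891 barcodes. The accessibility libraries held 41001937 counts in 20094 barcodes (control) and 20144616 counts in 1969 barcodes (mutant). The depth of the whole-kidney libraries is unknown. Each single-cell or accessibility library is a pool of embryos of 1 sex, except that the mutant male single-cell libraries came from 1 embryo each, and each whole-kidney library came from 1 male embryo. Below, values are means ± SD over 2 libraries of each genotype unless single libraries are given, and changes are log2 of mutant over control.

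Tcf21 (ENSMUSG00000045680), a bHLH transcription factor of mesenchymal cells and the gene targeted here, was lower in the stromal cells of all 4 mutant libraries. At E14.5 it stood at 167 and 243 CPM in the control female and male and at 51.2 and 76.3 CPM in the mutants (log2 -1.69, edgeR adjusted p = 0.104). At E18.5 it stood at 529 and 263 CPM in the controls and 69.7 and 86.2 CPM in the mutants (log2 -2.37, edgeR adjusted p = 0.0764). Neither passed the threshold, and with DESeq2 in place of edgeR both did (adjusted p = 0.00938 and 9.09e-05; over all alternatives 2.32e-05 to 0.411 at E14.5 and 1.42e-05 to 0.388 at E18.5). In whole kidney Tcf21 was at 83.2 and 67.2 FPKM in controls and 59.4 and 59.5 FPKM in mutants (log2 -0.33, limma adjusted p = 0.414). The labels do not say which part of the gene is floxed, and 3′ tags outside a deleted part would still be counted, so these levels do not measure the deletion. Foxd1 (ENSMUSG00000078302), the gene whose promoter drives Cre, was at 250 ± 47.5 and 284 ± 11.9 CPM in control and mutant stroma at E14.5 (log2 0.19, adjusted p = 0.383) and at 118 ± 10.7 and 135 ± 12.4 CPM at E18.5 (log2 0.20, adjusted p = 0.426).

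The first comparison asked what Tcf21 mutation in the Foxd1 lineage changed in stromal cells at E14.5, during branching of the ureteric tree. Npy (ENSMUSG00000029819), which encodes neuropeptide Y, rose from 0.804 ± 0.349 to 44.0 ± 6.23 CPM (n = 2 each; log2 5.80, edgeR adjusted p = 2.38e-07). Egfl6 (ENSMUSG00000000402), a secreted matrix protein, rose from 14.4 ± 1.49 to 86.1 ± 11.9 CPM, and Cd44 (ENSMUSG00000005087), a hyaluronan receptor, from 4.36 ± 0.969 to 25.1 ± 1.41 CPM. The chemokine gene Cxcl13 (ENSMUSG00000023078) rose from 44.6 ± 2.95 to 201 ± 39.7 CPM (log2 2.17). Rxfp2, Rgs17, Lix1, Zfhx4 and Ebf2 also rose (log2 3.01, 2.77, 2.66, 2.31 and 2.16). Of the genes that fell, Nkain4 changed by log2 -2.25, and AA465934 (ENSMUSG00000093483) went from 60.2 ± 22.7 to 3.09 ± 0.166 CPM (log2 -4.30, adjusted p = 0.000137). Lrriq1 (ENSMUSG00000019892) went from 23.7 ± 5.34 to 3.40 ± 0.645 CPM, Ppp1r14a (ENSMUSG00000037166), which encodes an inhibitor of myosin phosphatase, from 100.1 ± 11.6 to 18.7 ± 1.57 CPM, and Rasgrp2 from 106 ± 13.9 to 30.9 ± 7.85 CPM. Rem1 and Ano4 fell as well (log2 -2.83 and -2.36). In all, 1398 genes rose and 1272 fell of 17363 tested. Without the control female, control male, mutant female or mutant male library of this stage the counts were 433 and 315, 720 and 561, 397 and 294, and 902 and 730, and with non-stromal clusters included they were 3 and 16. Cxcl13 did not pass without the control female library (log2 2.1, edgeR adjusted p = 0.0599) and Nkain4 without the control or mutant female (-2.24, 0.0545, and -2.10, 0.0698).

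Among the gene groups at E14.5, the stroma-to-epithelium signals divided. Of 12 measured, 3 rose, 1 fell and 8 did not pass (adjusted over the list alone, 5 rose and 1 fell; camera adjusted p = 0.213). Gdnf (ENSMUSG00000022144), which encodes the main ligand for ureteric branching, fell from 41.7 ± 3.90 to 14.7 ± 2.64 CPM (log2 -1.51, edgeR adjusted p = 0.00551; 0.0583 without the control female library), while Fgf7 and Rspo3 rose (log2 1.13 and 0.89; without the mutant female library Rspo3 was at 0.76, adjusted p = 0.0844). Of 10 perivascular markers, 1 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.329): Acta2, smooth muscle actin, fell from 135 ± 22.5 to 63.4 ± 10.7 CPM and Rgs5 rose (log2 1.22). Without the mutant female library these were at log2 -1 (adjusted p = 0.0638) and 1.27 (0.0629). Of 6 medullary stroma markers, 2 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.0745, and 0.600 with an estimated correlation; fry, lower, 0.0418). Alx1 fell from 65.2 ± 2.14 to 18.8 ± 0.0924 CPM. Notch targets were 0 higher and 2 lower of 7 (1 and 2 adjusted over the list alone; camera adjusted p = 0.0935), with Hey2 and Heyl both falling (log2 -1.05 and -1.04). Of 9 basement membrane genes 3 rose and 3 fell (4 and 3 adjusted over the list alone; median 0.09, mean -0.03, camera adjusted p = 0.871), Col4a1 falling from 287 ± 20.1 to 143 ± 16.2 CPM. The camera test called 4 lists, all higher: early nephron markers (2 of 4 rose, Cdh6 by log2 1.32; adjusted p = 0.000322), dissociation stress genes (5 of 10 rose, Jun from 64.8 ± 8.93 to 143 ± 3.06 CPM; 0.000322), endothelial markers (3 of 7 rose and 1 fell, Emcn from 25.6 ± 1.05 to 101 ± 0.576 CPM; 0.00611) and nephron progenitor markers (1 of 5 rose, Meox1; 0.0386). Adjusted over the list alone the counts were 3 and 0, 5 and 0, 3 and 1, and 1 and 0. With an estimated correlation their adjusted p = 0.374, 0.374, 0.600 and 0.600, so none was called (2 of 33 lists at an unadjusted p under 0.05). Fry called the early nephron and dissociation stress lists (0.0418 each). The endothelial list had a median of -0.13 beside a mean of 0.51. In the same cells 26 genes abundant in nephron cells stood at a median of 5.26% and 5.08% of their nephron level in controls and 6.61% and 6.87% in mutants, and 23 of the 26 were higher in mutants of each sex.

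**Figure D1:**
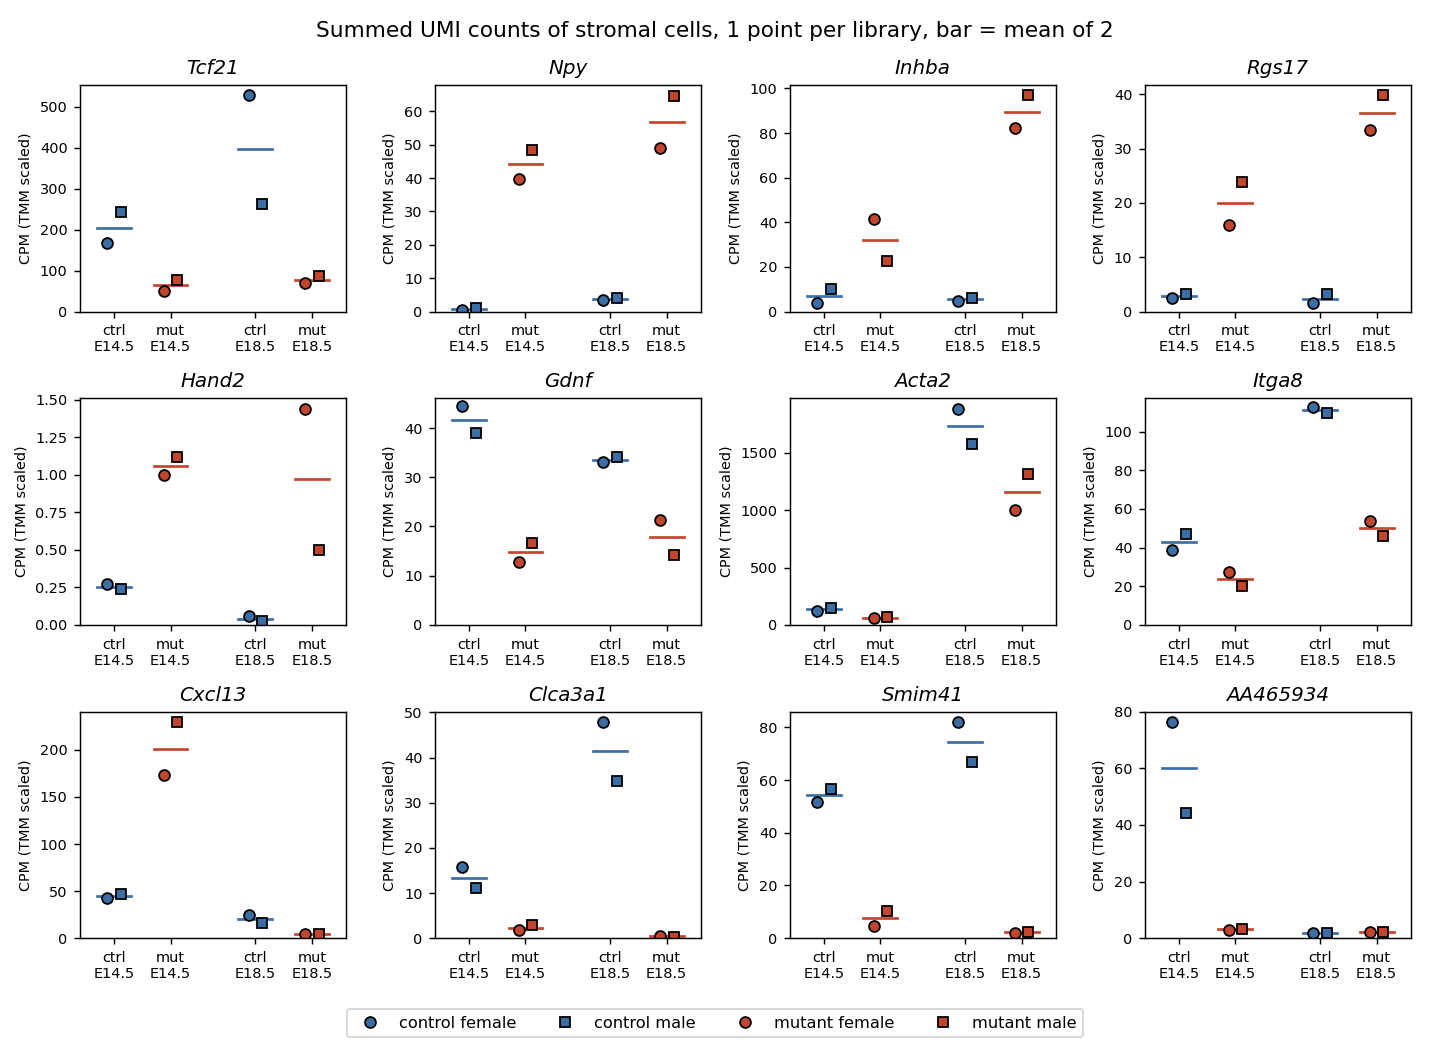
Levels of 12 genes in stromal cells (CPM with TMM factors) in each of the 8 single-cell libraries, by stage and genotype, with each point 1 library and each bar the mean of 2. Tcf21 was lower in each mutant library than in either control library of its stage, and Npy was at 0.804 CPM on average in E14.5 controls and 44.0 CPM in mutants.

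The second comparison asked the same question at E18.5. Npy rose from 3.83 ± 0.527 to 56.9 ± 11 CPM (log2 3.90, edgeR adjusted p = 1.48e-06) and Rgs17 from 2.39 ± 1.15 to 36.6 ± 4.58 CPM. Inhba (ENSMUSG00000041324), a subunit of activin and inhibin, rose from 5.57 ± 1.04 to 89.5 ± 10.4 CPM (log2 4.00, adjusted p = 0.0398). Fabp4 (ENSMUSG00000062515), a fatty acid binding protein of adipocytes and endothelium, rose from 11.1 ± 0.966 to 46.9 ± 16.8 CPM. Ptprz1, Ecrg4, Khdrbs2 and Stc1 also rose (log2 3.66, 2.62, 2.61 and 2.01). Clca3a1 (ENSMUSG00000056025), a cortical interstitium marker, fell from 41.3 ± 9.13 to 0.436 ± 0.118 CPM (log2 -6.49, adjusted p = 0.00037). Alx1 (ENSMUSG00000036602) fell from 56.8 ± 4.98 to 9.71 ± 0.579 CPM, Nts, which encodes neurotensin, from 144 ± 35.4 to 18.9 ± 1.96 CPM and Smim41 from 74.4 ± 10.8 to 2.24 ± 0.358 CPM (log2 -5.08; without the mutant female or male library adjusted p = 0.114 and 0.123). Lrriq1, Cxcl14 and Frem1 fell too (log2 -4.70, -3.31 and -2.51). In all, 872 genes rose and 748 fell. Without the control female library these counts were 383 and 376 and without the control male 419 and 490, 566 genes rose without the mutant male, 482 fell with the E18.5 libraries alone, and 2 and 11 rose and fell with non-stromal clusters included. Inhba kept log2 values of 3.91, 4.1, 3.99 and 4.00 without the control female, control male, mutant female and mutant male library, but its adjusted p was then 0.220, 0.255, 0.217 and 0.276.

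At E18.5 camera with its preset correlation called 6 lists, and none was called with an estimated correlation (3 of 33 at an unadjusted p under 0.05). Fry called 4 of the 6, the nephrogenic-zone, medullary, endothelial and adipogenic lists (adjusted p = 0.0378 each). Of 5 nephrogenic-zone markers, 2 rose over all genes and adjusted over the list alone, Rspo3 from 24.6 ± 2.94 to 84.3 ± 10.2 CPM and Aldh1a2, a retinoic acid synthesis enzyme, from 139 ± 1.31 to 270 ± 17.4 CPM (camera adjusted p = 0.000129; adjusted p = 0.460 with an estimated correlation). Of 6 medullary markers 1 rose, Lef1, and 1 fell, Alx1, with the same counts adjusted over the list alone (camera lower, adjusted p = 0.00852; adjusted p = 0.460 with an estimated correlation). Endothelial markers were 3 higher and 0 lower of 7 (4 and 0 adjusted over the list alone; camera adjusted p = 3.73e-06; adjusted p = 0.460 with an estimated correlation). Emcn rose from 71.3 ± 7.83 to 232 ± 22.7 CPM, and Kdr from 0.599 ± 0.172 to 2.38 ± 0.335 CPM. Adipogenic genes were 2 higher of 5, Fabp4 and Pparg (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0431; adjusted p = 0.460 with an estimated correlation). Camera also called erythroid markers higher (1 of 5 rose, Alas2 from 0.0844 to 1.60 CPM; adjusted p = 0.00597, and 0.582 with an estimated correlation) and cartilage markers lower (1 of 4 fell, Col9a1; adjusted p = 0.0268, and 0.460 with an estimated correlation). Each of these lists had the same count adjusted over the list alone. Hemoglobin RNA was unequal between these libraries: Hbb-bs stood at 4.27 and 18.8 CPM in control stroma and 648 and 452 CPM in mutant stroma, with reads that its near-identical paralog could share. Of 12 stroma-to-epithelium signals 1 rose and 2 fell, as adjusted over the list alone (camera adjusted p = 0.487), and Gdnf fell from 33.5 ± 0.713 to 17.8 ± 4.97 CPM (adjusted p = 0.0403). That call ended without the control female (log2 -1.01, adjusted p = 0.158), control male (-0.82, 0.242) or mutant male library (-0.62, 0.0580). Of 5 mesangial markers 1 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.506), with Itga8 at 111 ± 2.17 CPM in controls and 49.98 ± 5.46 CPM in mutants (adjusted p = 0.00439, and 0.0568 and 0.0578 without the control female and male library). Of 11 bHLH factors and Id proteins 2 rose and 4 fell (4 and 4 adjusted over the list alone; median 0.03, mean -0.09, camera adjusted p = 0.721). Among them Id4 fell from 37.5 ± 3.88 to 11.9 ± 4.01 CPM (adjusted p = 0.00748, and 0.0510 without the mutant female), and Tcf12 from 120 ± 1.91 to 83.7 ± 2.37 CPM.

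A further comparison asked whether the effect differed between the stages. The difference of the effects was more positive at E18.5 for 73 genes and more negative for 118. Cxcl13 was at 42.5 and 46.7 CPM in controls and 173 and 229 CPM in mutants at E14.5, and its change at E18.5 was log2 -2.27 (difference -4.44, edgeR adjusted p = 0.0120). Without the E14.5 control female or either E18.5 mutant library that adjusted p was 0.0698, 0.0624 and 0.0726. AA465934 fell at E14.5 and had a change of log2 0.15 at E18.5 (difference 4.45, adjusted p = 0.00501). At E18.5 it stood at 1.85 and 1.93 CPM in controls and 2.32 and 2.08 CPM in mutants. These levels lie under the 2.97 and 3.21 CPM of the E14.5 mutants, so a fall like that at E14.5 could not show there. Epha4, an ephrin receptor, had changes of log2 0.83 and -1.61 (difference -2.44, adjusted p = 0.000111), Nefm of 1.70 and -0.45 and Klf4 of 1.05 and -0.94. Khdrbs2 had changes of 0.74 and 2.61, and Clca3a1 of -2.65 and -6.49. Counts of this contrast were 209 and 342 with DESeq2 and 179 and 244 without a low-count filter. They were 27 and 47, 32 and 45, and 31 and 77 without the E14.5 control female, mutant female and mutant male library. Without the E18.5 control female they were 20 and 45, without the E18.5 mutant female 135 and 179, and without the E18.5 control male 34 were more positive. For this contrast camera called 12 lists (the smallest adjusted p, 8.77e-05, for cartilage and ureteric epithelium markers, more negative at E18.5), while 0 were called with an estimated correlation (3 of 33 at an unadjusted p under 0.05) and 0 with fry (6 of 33). Between the stages, 484 genes rose in both and 366 fell in both, against 70.2 and 54.8 if the lists were independent, and 26 and 9 went opposite ways. Of 2670 genes called at E14.5, 83.2% had the same sign at E18.5, against 63.5% of all 17356 genes tested at both stages.

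Within classes of stromal cells the question was which changes stood inside 1 class. In nephrogenic-zone stroma-like cells at E18.5 (mostly cluster 8 in controls and cluster 4 in mutants) 1055 genes rose and 903 fell of 14686, among them Npy (log2 6.01), Egfl6 (5.77) and Inhba (4.02) upward and Smim41 (-4.69), Rem1 (-3.35) and Ggt5 (-2.71) downward. Mutant cells made up 1.6% of cluster 8 and 98.6% of cluster 4, so the clustering had already parted the genotypes, and Npy was among the leading genes of cluster 4. These calls thus compare unlike clusters, and their p-values do not allow for that. In medullary stroma-like cells at E14.5 (cluster 9) 498 rose and 355 fell, with Plcxd3 (4.2), Shisa2 (3.36), Twist1 (2.41), AA465934 (-3.97), Sostdc1 (-3.07) and Acta2 (-2.34). In mural-like cells 161 rose and 108 fell at E14.5 (cluster 16), with Ccl2 (2.25), Smim41 (-4.34) and Gdnf (-2.04), and 81 rose and 102 fell at E18.5 (clusters 11 and 15), with Fabp4 (2.53). In cortical interstitium-like cells 12 rose and 73 fell at E14.5 (cluster 10) and 6 rose and 16 fell at E18.5 (cluster 20). There Ren1, which encodes renin, was at 25.9 and 117 CPM in controls and 4.13 and 12.5 CPM in mutants at E14.5, and at 20.8 and 42.6 CPM against 76.2 and 274 CPM at E18.5 (difference of log2 changes 5.50, edgeR adjusted p = 3.19e-06). Clusters 10 and 20 shared the leading genes Dcn, Lum and Igf1 and differed in the others, such as Cxcl13 against Prss35 and Colec11. With classes from control cells only, the E18.5 class held 0 and 4 control and 74 and 20 mutant cells. The E18.5 cluster led by Prss35 and Colec11 was then unnamed, with the perivascular list best supported. The stage difference of Ren1 may thus compare unlike cell types. Nephrogenic-zone stroma-like cells at E14.5 and medullary stroma-like cells at E18.5 had under 50 cells in a library and were not tested. Nephrogenic cells had 1138 calls without the E18.5 control male. Medullary cells had 475, 442 and 389 without the E14.5 control female, mutant female and mutant male. E14.5 mural cells had 149, 92, 56 and 151 without the control female, control male, mutant female and mutant male of that stage and 420 without the E18.5 mutant male, and E18.5 mural cells had 48 without the E18.5 control male. E14.5 cortical cells had 135, 39 and 47 without the control female, mutant female and mutant male. E18.5 cortical cells had 64 and 63 without the E14.5 control female and male, and 8, 8 and 3 without the E18.5 control male, mutant female and mutant male.

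Shares of cell classes depend on the sort for the Foxd1 lineage and, for stromal classes, on genes that themselves changed. Mural-like cells were 9.81% and 5.66% of retained cells in E14.5 controls and 1.41% and 0.694% in E14.5 mutants, and 13.7% and 17.8% against 15.8% and 15.3% at E18.5. Over the 4 pairs the mean log2 odds ratio was -1.51 (two-sided exact sign-flip p = 0.25, where 4 pairs cannot reach 0.05; lower in 3 of 4 pairs). These shares depend on the clustering: at a lower resolution they were 2.47% and 0.988% in E14.5 controls and 0.810% and 0.360% in mutants (mean log2 odds ratio over the 4 pairs -0.78), at a higher one 2.05% and 0.782% against 0.486% and 0.219% (-1.08), and with classes from control cells only 9.72% and 6.07% against 4.32% and 1.31% (-0.88). Over stromal cells alone the E14.5 mural-like shares were 10.6% and 8.22% in controls and 1.69% and 2.73% in mutants. The log2 odds ratios were then -2.77 in females and -1.66 in males, against -2.92 and -3.09 over retained cells. At the lower resolution the shares of stromal cells were 2.67% and 1.44% in controls and 0.972% and 1.42% in mutants (-1.47 and -0.0028). With edgeR on the cell counts of each class out of retained cells, the mural-like change was log2 -2.89 at E14.5 (adjusted p = 0.00355) and -0.05 at E18.5 (0.961), with a difference of 2.84 (0.0264). The mural-like cells of E14.5 were mostly cluster 16, best supported by perivascular markers. Those of E18.5 were mostly clusters 11 and 15, best supported by mesangial and renin cell markers, so the difference compares unlike clusters. At E14.5 early nephron-like, podocyte-like, neural-like and other non-stromal shares rose (1.75, 2.49, 3.14 and 1.82). Neural-like shares were 0.0632% and 0.103% in controls and 0.178% and 2.30% in mutants, so this rise lay mostly in the mutant male library, which came from 1 embryo. Podocyte-like shares were 0.0211% and 0.154% in controls and 0.194% and 0.772% in mutants. At the lower resolution they were 0.0211% and 0.0309% against 0.0648% and 0.309%. With classes from control cells only they were 0.0105% and 0% against 0% and 0%, so this rise depends on how the classes were made. The nephrogenic-zone stroma-like share at E14.5 and the medullary stroma-like share at both stages also passed as lower (-5.18, -2.68 at E14.5 and -7.36 at E18.5), but the first and the last depend on how the classes were made, since unnamed clusters of mostly mutant cells had the same markers raised (97.5% mutant in cluster 3 and 100% in cluster 12). With classes from control cells only, nephrogenic-zone shares of retained cells at E14.5 were 31.9% and 18.4% in controls and 26.9% and 9.003% in mutants, and medullary shares 24.6% and 16.8% against 8.77% and 2.32% at E14.5 and 8.75% and 9.16% against 10.0% and 10.2% at E18.5. The E14.5 nephrogenic-zone class then held 3031 and 1792 control and 1664 and 700 mutant cells. Stromal cells numbered 8804 and 6687 in controls and 5134 and 1978 in mutants, so the lower male share did not hold over stromal cells. Acta2, a marker that defines the mural-like class, fell at E14.5, and Rgs5 rose, so no difference in cell number is read from these shares. Cells outside the stroma made up 7.31% and 31.2% of retained cells in E14.5 controls and 16.9% and 74.6% in mutants (E18.5: 7.53% and 11.1%, then 3.30% and 7.63%; exact p = 0.625 over the 4 pairs).

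**Figure D2:**
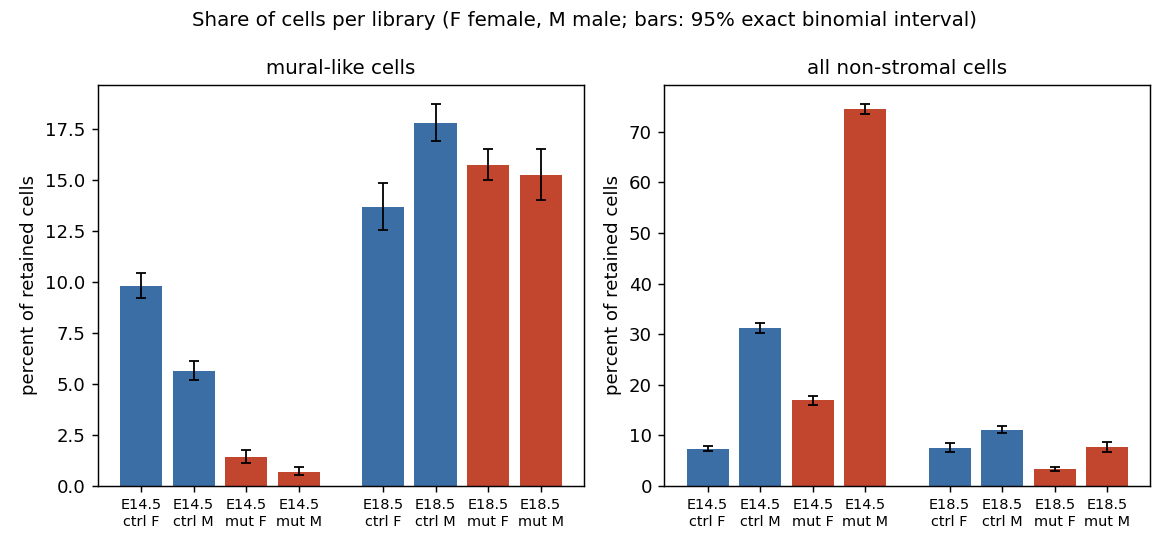
Percent of retained cells that were mural-like and percent that were outside the stroma in each of the 8 single-cell libraries, with 95% exact binomial intervals that cover counting error only. The E14.5 mutant male library held 74.6% of its cells outside the stroma.

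Outside the stroma of E14.5 libraries EGFP, the reporter transcript made after Cre activity, was measured in nephron progenitor-like cells at 190 and 1086 CPM in the control female and male and 1075 and 1180 CPM in the mutants. AA465934 was at 66.0 and 4.59 CPM in nephron progenitor-like cells of the control female and male, and Cwc22 at 82.3 and 236 CPM.

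**Figure D3:**
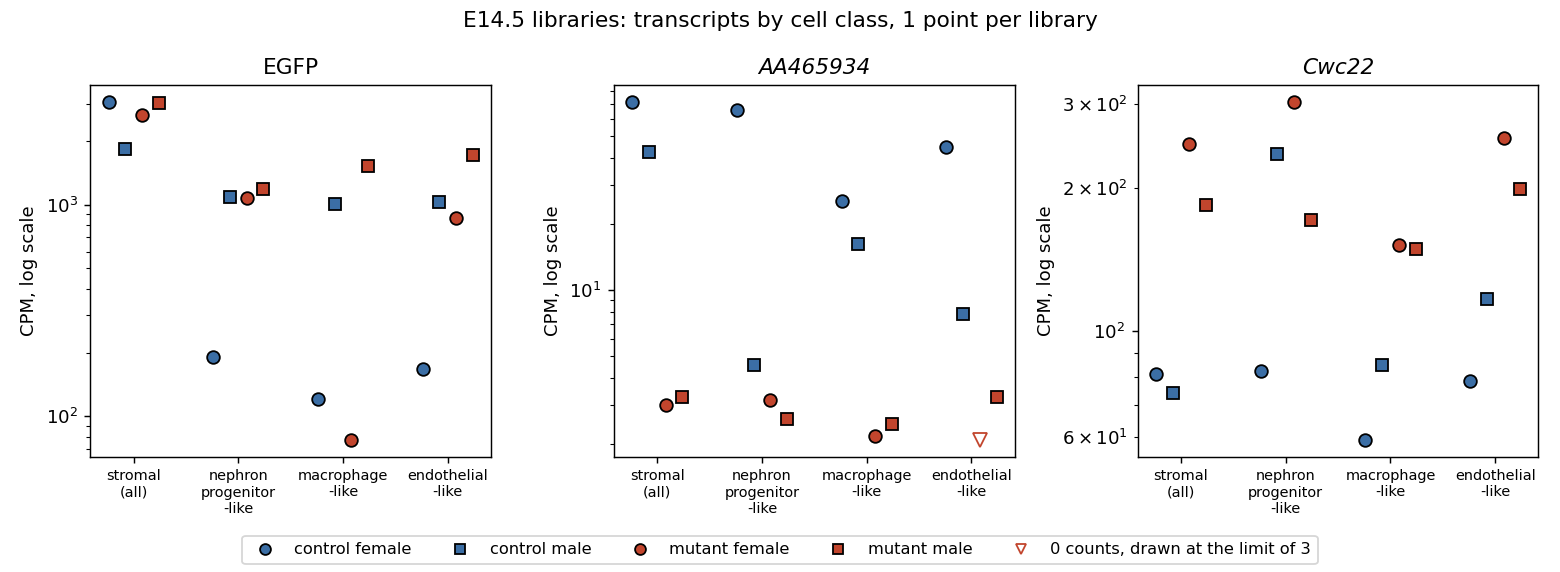
EGFP, AA465934 and Cwc22 (CPM, log axis) by cell class in the 4 E14.5 single-cell libraries, with each point 1 library and an open triangle at the limit of 3 counts where 0 were counted. AA465934 in nephron progenitor-like cells was at 66.0 CPM in the control female and 4.59 CPM in the control male.

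The whole-kidney comparison asked which changes could be seen without dissociation or sorting. Inhba was at 1.06 and 1.39 FPKM in controls and 15.4 and 11.3 FPKM in mutants (log2 2.68, limma adjusted p = 0.00365). Among the genes with the largest rise were several that encode proteins of striated muscle fibres, a grouping made after their values were seen: Myh8 from 0.225 ± 0.205 to 10.8 ± 0.799 FPKM, Tnnc2 from 4.23 ± 1.29 to 30.9 ± 1.84, Acta1 from 8.47 ± 4.4 to 49.1 ± 0.912 and Tnnt3 from 6.34 ± 0.905 to 26.6 ± 4.09, with Tnni2 and Atp2a1 (log2 2.34 and 1.91). Of the 3 measured skeletal muscle markers of the fixed list 0 passed, and 2 rose adjusted over the list alone (camera adjusted p = 0.128; 0.663 with an estimated correlation). Tceal7, Rxfp2 and Atp1b4 rose as well (log2 2.32, 1.94 and 1.74). Col6a4 fell from 7.22 ± 1.75 to 0.435 ± 0.474 FPKM, Nts from 30.7 ± 2.06 to 7.45 ± 1.69, Alx1 from 20.7 to 5.91 ± 0.750 and Clca3a1 from 13.5 ± 0.523 to 3.13 ± 1.41, and Cck and Srpx2 fell too (log2 -2.06 and -1.89). Without a low-value filter 19 of 38 values of named genes in whole kidney lost their call. Over all alternatives the highest adjusted p was 0.238 for Myh8, 0.148 for Clca3a1, 0.126 for Srpx2, 0.117 for Acta1, Tnni2, Col6a4 and Cck, 0.105 for Atp2a1, 0.0858 for Rxfp2, 0.0774 for Atp1b4, 0.0668 for Tceal7 and 0.0570 for Inhba, and 0.0369 for Tnnc2, 0.0410 for Tnnt3, 0.0455 for Nts and 0.0341 for Alx1. Several of the largest values belonged to small RNA genes: Mir29b-2 was listed at 0 in both controls and at 83.1 and 204 FPKM in the mutants, and Snord42b at 603 and 424 FPKM in controls and listed at 0 in both mutants. Large values of such genes can stand for few fragments: for 70.4% of 54 small RNA genes in controls and 61.0% of 41 in mutants, the ratio between the kidneys of a genotype was a common factor times a ratio of whole numbers up to 6 (tolerance 0.3%), against 3.29% and 3.37% of random ratios. Camera called early nephron markers higher (adjusted p = 0.0485) and proliferation markers and Notch targets higher and interferon genes lower (0.0213 each). No member of these lists passed over all genes, and adjusted over the list alone 3 Notch targets rose and 3 interferon genes fell. With an estimated correlation adjusted p = 0.663 for each of the 4 lists. In all, 32 genes rose and 69 fell of 15131. Without control 1 the counts were 28 and 25, without control 2 66 and 106, without mutant 1 138 and 483 and without mutant 2 100 and 360. They were 8 and 15 with no low-value filter and 18 and 31 without the trend. Of genes tested in E18.5 stroma and in whole kidney, 10 rose and 30 fell in both, against 1.15 and 1.90 if independent, and 0 went opposite ways.

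The accessibility libraries asked whether the open regions of E14.5 kidney nuclei differed, with 1 library per genotype and so no test. Of 102799 control and 94382 mutant peaks, 73.1% and 79.5% overlapped a peak of the other library, and these held 92.2% and 94.4% of the counts in peaks. The covered lengths were 88.6 and 81.8 Mb, at 463 and 246 counts per kb. The median barcode held 464 counts in the control and 10389 in the mutant library, so calls at low signal are not comparable. At Tcf21 (mm10 chromosome 10, 22817263 to 22820143) a control peak at 22819696 to 22820493 held 15.5 CPM (95% exact interval 14.3 to 16.8, counting error only) and had no counterpart among the mutant peaks. Mutant peaks at 22811905 to 22812790, 22814643 to 22815570 and 22816038 to 22816875 (4.07, 8.74 and 6.60 CPM) had none among the control peaks. The regions shared by both libraries within 5 kb of the gene held 29.9 CPM in the control and 30.2 CPM in the mutant (log2 0.01). A peak in the gene body was called in both, at 7.59 CPM in the control and 9.23 CPM in the mutant. The peak at the start of Foxd1 held 38.8 and 41.9 CPM. Signal in shared regions within 5 kb of Clca3a1 was 7.81 CPM in the control and 3.10 CPM in the mutant (log2 -1.21), around Emcn 3.18 and 6.99 CPM (1.03) and around Tbx18 49.8 and 71.3 CPM (0.51), while Acta2 and Gdnf had log2 ratios of 0.05 and -0.03. Peaks without a counterpart in the other library are left out of these values, so a small ratio does not exclude a lost or gained peak. Among 10000 matched random lists the ureteric stroma list ranked at percentile 98.7 (median log2 0.13), Wnt targets at 9.22 (-0.06) and the retinoic acid list at 10.1 (-0.08). With barcodes matched on number and depth these percentiles were 96.7, 84.0 and 57.1. Posterior Hox genes had a median of 0.09, and no percentile is given because neighbouring members share regions while the random lists hold scattered genes.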

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

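The tests of EGFP over matrix RNA and of pooled embryos of different background were chosen only after those results were seen, and so were the genes Cwc22 and Dera, the reading of endothelial-like cells and the reading of macrophage-like clusters apart.

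EGFP, the transcript that the reporter makes after Cre activity, appeared outside the stroma: in nephron progenitor-like cells it stood at 1180 CPM in the E14.5 mutant male library, against 190 CPM in the control female, 1086 CPM in the control male and 1075 CPM in the mutant female, and 3007 CPM in the stromal cells of the same mutant library. This was a signal in data outside the main comparisons. Stromal RNA, free or from doublets, would bring fibrillar matrix RNA in the same ratio, but in macrophage-like cells of the mutant male the EGFP ratio to stroma was 11.656 times the matrix ratio, which argues against it there. That class joined 2 clusters: in the 48 cells of cluster 26, led by macrophage genes, the figure was 35.9, and in the 77 of cluster 30, whose leading genes include the lymphoid genes Ltb, Il7r and Trbc2, it was 6.32. The class also held RNA of the nephron progenitor list at 183 CPM, against 2.69 CPM in the control male (39.3 CPM in cluster 26 and 341 CPM in cluster 30). In the control female the figure over the class was 0.959, which goes with free RNA as the source. In cluster 26 alone it was 22.7 in the control male and 1.35 in the mutant female, so it was high in both male and low in both female libraries and did not follow the genotype. Cre activity outside the stroma that also deleted Tcf21 cannot be told apart: Tcf21 in podocyte-like cells was 1.854 times as high in the mutant male as in the control male (interval 1.44 to 2.41, counting error only), and the outcome set beforehand as speaking against it was met. That outcome assumed that tags follow the deletion, while the labels do not give the floxed part and 3′ tags outside it would still be counted. In all E14.5 stromal cells, where Cre is expected to act, the change of log2 -1.69 did not pass the threshold with edgeR (adjusted p = 0.104). It passed with DESeq2, and Tcf21 was lower in both mutant libraries. A lower level alone does not show that the tags measure the deletion. EGFP was above tdTomato in 100% of nephron progenitor-like cells of the mutant male and 99.05% of those of the control male. In ureteric epithelium-like cells these shares were 99.8% and 99.06%, with EGFP at 1196 and 1226 CPM. In nephron progenitor-like cells of the females the shares were 80.7% (mutant) and 46.8% (control). In the E14.5 males EGFP thus did not mark stromal cells alone. How cells of these classes came to hold EGFP stays open, and the sort was for EGFP.

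AA465934 differed between stages: its effect was more positive at E18.5 by 4.45 on the log2 scale. In stroma it stood at 1.85 and 1.93 CPM in E18.5 controls, against 76.3 and 44.2 CPM in E14.5 controls, so no such fall could show at E18.5. In nephron progenitor-like cells of the E14.5 libraries its mean log2 ratio was -2.594 (-4.37 in females and -0.81 in males). A difference between pools that acts in all cell types cannot be told apart from other explanations, because the control male held only 0.108 of its stromal level there. In macrophage-like cells of the females the ratio was -3.551 (upper bound -1.59). EGFP stayed near the level of free RNA there: its ratio to stroma was 0.958 times the matrix ratio in cluster 26 of the control and 1.35 times in that of the mutant. But the control level of AA465934 was 0.356 of that in stroma, under the bound set beforehand, and this rests on the female libraries. Loss of Tcf21 in stroma as the whole cause thus also cannot be told apart. Endothelial-like cells of the control female held 44.7 CPM, 0.624 of the stromal level, and those of the mutant female 0 counts (limit 2.09 CPM), which goes against it, but EGFP stood at 862 CPM in those mutant cells, against 167 CPM in the control, so Cre activity there is not excluded, and this rests on the female libraries: in males the control held 0.184 of the stromal level. In the control male library Cwc22 was 3.181 times as high in nephron progenitor-like as in stromal cells, and AA465934 0.108 times, while the control female had 1.02 and 0.920. Dera did not show this: it was at 1.10 times its stromal level in the control male and 1.11 in the control female, and its log2 ratios of mutant over control in nephron progenitor-like cells were -0.38 in females and -0.36 in males. Those of Cwc22 were 1.88 in females (interval 1.74 to 2.02, counting error only) and -0.46 in males. Within the control male library the values of AA465934 and Cwc22 go with embryos of different genetic background pooled there, a hypothesis found and tested on the same data. It does not cover the differences of both genes between the control and mutant female libraries, whose cause was not settled.

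The other stage differences in stromal cells were 1.87 for Khdrbs2, 1.69 for Hopx, 1.53 for Gimap6 and 1.48 for Dera, and -4.44 for Cxcl13, -3.85 for Clca3a1, -2.44 for Epha4, -2.15 for Nefm and -1.99 for Klf4. Ren1 had a stage difference of 5.50 in cortical interstitium-like cells. That class was mostly cluster 10 at E14.5 and cluster 20 at E18.5, so unlike cell types cannot be told apart from a change with stage. All of these stage differences passed the test of the difference between the stages. With 1 library left out, 59 values of the 10 named stromal genes kept that call and 21 lost it, and all 10 lost it with all retained cells summed.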

How the results depend on the processing

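Excluding small RNA genes and genes at 0 in any kidney were alternatives chosen after seeing the data, and both left the whole-kidney counts within 1.5 times; all others were planned before. Where leaving out a library left 1 in an arm, that library was assumed to vary like the other groups. Each of the 8 single-cell libraries was left out in turn for every contrast. Ranges and kept calls given below for a single stage thus include omissions of libraries of the other stage, which are in neither arm. They do not give the share kept when only that stage's own libraries are left out. For 1 library left out, counts ranged from 397 to 1557 higher and 294 to 1412 lower at E14.5, 383 to 848 and 376 to 715 at E18.5, 20 to 135 and 45 to 179 for the stage difference, and 28 to 138 and 25 to 483 in whole kidney. In classes they ranged from 1138 to 1945 (nephrogenic), 389 to 1200 (medullary), 56 to 420 and 48 to 205 (mural at E14.5 and E18.5) and 39 to 135 and 3 to 64 (cortical). With all retained cells summed, 3 rose and 16 fell at E14.5, 2 and 11 at E18.5, and 0 and 0 differed between stages, since cells outside the stroma, at 7.31% to 74.6% of E14.5 libraries, then entered the sums. In those sums Hgf (-0.22), Cdkn1c (-0.22), Tgfbi (-0.0232), Fn1 (-0.25) and Col3a1 (-0.27) at E14.5 and Cdh6 (-0.31) at E18.5 turned sign. DESeq2 gave 209 and 342 for the stage difference and 647, 405 and 106 calls in nephrogenic, medullary and E18.5 mural cells, and no low-count filter gave 179 and 244. Classes from control cells only gave 1494 (medullary), 533 (mural) and 171 (cortical) at E14.5, and moved the log2 odds ratio of cortical shares from 0.15 to 2.77 of retained and from 0.56 to 3.22 of stromal cells. No sex covariate gave 13 calls in E18.5 cortical cells, and the E18.5 libraries alone gave 482 lower. In whole kidney no low-value filter gave 8 and 15, a mean of at least 5 FPKM 20 higher, quantile normalization 33 lower and no trend 18 and 31. The mural share of retained cells passed with edgeR on cell counts (-1.47 over both stages, adjusted p = 0.0297), from E14.5 (-2.89) and not E18.5 (-0.05). Called lists went from 4, 6 and 4 to 0 with an estimated correlation, and 0 in whole kidney with fry; for the stage difference they went from 12 to 0 with both. Shared control and mutant peaks were 72.1% and 78.5% at 50% reciprocal overlap, and 97.4% and 26.1% for peaks in at least 1.0% of barcodes, where depth per barcode sets which peaks remain. Apart from these constructions the cause was not tested. Of named genes with 1 library left out, 540 values kept their call and 105 lost it at E14.5, 464 and 94 at E18.5, 59 and 21 for the stage difference, and 106 and 8 in whole kidney. No paired analysis was possible because the columns carry no sample number in whole kidney, so the planned replicate block was not run there; the single-cell fits held sex as a covariate.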

Other observations

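The analysis of genes around Tcf21 and the reading of stromal calls in nephron cells were chosen after the calls were seen, and the expected outcomes of the neighbour tests were written before their values.

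Tcf21 was measured in classes of E14.5 stroma. In medullary stroma-like cells it stood at 382 and 552 CPM in controls and 331 and 491 CPM in mutants (log2 -0.19, edgeR adjusted p = 0.905), while in mural-like cells it stood at 65.6 and 115 CPM in controls and 15.1 and 12.7 CPM in mutants (log2 -2.59, adjusted p = 0.192), and in cortical interstitium-like cells at 25.31 and 41.46 CPM in controls and 32.0 and 20.5 CPM in mutants (log2 -0.34, adjusted p = 0.883). The medullary values come from 100 and 138 mutant cells against 1140 and 931 control cells, the mutant cells that still clustered with control cells. Medullary stroma-like cells of mutants held 498 genes that rose and 355 that fell. The difference between the classes was not tested, and 3′ tags do not show whether the transcript was intact.

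Genes of striated muscle fibres that rose in whole kidney, grouped after their values were seen, were not called in E18.5 stromal cells where tested: Acta1 was at log2 -1.19 (adjusted p = 0.413), Tnni2 at -0.38 (0.694), Atp2a1 at -0.44 (0.866) and Tnnt3 at 0.46 (0.119). Myh8 and Tnnc2 had too few counts there to be tested, and of the 3 measured skeletal muscle markers of the fixed list 0 passed in whole kidney. In E18.5 stromal cells fry called that list lower (adjusted p = 0.0382), while camera did not (0.0753, and 0.460 with an estimated correlation), and 1 of its 3 measured members fell. Genes that moved in both included Rxfp2 (3.46 in stroma), Col6a4 (-6.22), Nts (-2.93), Srpx2 (-2.37) and Apba1 (-2.25).

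Genes within 10 Mb of Tcf21 were called more often than elsewhere: 14 of 83 (16.9%) were called the same way at both stages, against 5.11% elsewhere. They include Moxd1 (log2 2.41 and 5.55), Eya4 (0.72 and 1.25), Hebp2 (-2.52 and -1.98), Tbpl1 (0.72 and 0.63), Rspo3 and Hey2; Raet1d and Raet1e have near-identical paralogs and Gm10824 overlaps Tcf21, so those 3 are uncertain. Of 129 other windows 1 (0.775%) held as large a share, at 18.2%. That lies under the bound set beforehand, which argues against a share that is common elsewhere, but 1 other place did reach it. The 3 uncertain genes are among the 14, and the rank was not taken without them. DNA inherited beside the floxed allele could act in all cell types, and 55.6% of the 9 members expressed in nephron progenitor-like cells lay on the stromal side there in both sexes. Their median change, signed along the stromal change, was 0.157. The uncertain genes Raet1d and Raet1e lay on that side, at 0.860 and 0.563, and these figures were not taken without them. Neither DNA inherited beside the floxed allele nor loss of Tcf21 in stromal cells as the whole cause can be decided: both values fell between the bounds set beforehand, and Tcf21 stood at 41.8 and 74.1 CPM in nephron progenitor-like cells of controls, where EGFP leaves Cre activity open, so these 2 cannot be told apart.

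Of 917 E14.5 stromal calls with a change of at least 1 on the log2 scale, 52 passed 2 floors in both sexes. These were on the stromal level and on the nephron progenitor-like level relative to it, with no upper limit on the latter. In nephron progenitor-like cells 2 of the 52 changed in the same direction by that much in both sexes. By sex, 10 of 58 did so in females and 2 of 56 in males, and 0 changed by that much in the opposite direction in either.

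Of small RNA genes in whole kidney, 14 were above 0 in both kidneys of 1 genotype and at 0 in both of the other, against 15 and 17 in the other pairings of the 4 kidneys.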
